A study of Saccharomyces cerevisiae with 9 samples.

How the data were processed

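The data are 9 scanner files of two-colour Agilent yeast arrays and a deposited matrix of log ratios. Per the labels, total RNA was extracted with a silica matrix, amplified with the Agilent low input linear amplification kit and labelled with the Micromax system at an outside service laboratory. Growth conditions are not given in the sources used here. Per the file headers, spots were read with Agilent Feature Extraction 9.5.3.1. Spot signals are deposited as intensity, per the file headers, and the deposited matrix holds log10 ratios of processed mutant over processed reference signal, already turned for the dye swaps, within 4.22e-06 of the values recomputed here. Each mutant has 3 biological replicates with 1 dye swap: array 2 of L3733A, array 2 of SRR3413_L3733A and array 1 of G3745 carry the mutant in Cy3. Dyes and directions come from the labels.

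Arrays 1 and 2 of L3733A are of a smaller design with 10807 features and 1 to 2 spots per probe, and the other 7 arrays of a larger design with 45209 features and 7 spots per probe. Slide 1 holds arrays 1 and 2 of L3733A, slide 2 holds array 3 of L3733A and arrays 1 and 2 of G3745, and slide 3 holds the 3 SRR3413_L3733A arrays and array 3 of G3745. Each of 6256 genes has 1 probe present on all 9 arrays, so 0 genes were left out. Names of 5756 genes were matched to the gene table by locus tag, and 500 kept the name on the array. The 272 probes below background in both channels on every array and the 19 saturated on any array were kept in the tests, and leaving them out was tried. A gene whose weaker channel was below background on all 3 arrays is given as a fold of at least its bound, and a gene below background in both channels on all 3 is given no fold. Correlations of mutants within a slide and signs per slide use log ratios with the fitted dye term removed.

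Mean signals were corrected with the median local background by normexp (offset 50) and normalized within each array by loess in limma 3.58.1 under R 4.3.3, with control spots given weight 0. Spots marked as outliers by the scanner software were dropped, and the remaining spots of a probe averaged. Files were read with the package data.table (version 1.17.8), and figures drawn with matplotlib 3.10.9 under Python 3.11.15. One linear model over the 9 arrays held a coefficient per mutant and 1 dye term shared by all arrays (5 residual degrees of freedom, 3.2 prior degrees of freedom from eBayes). Adjusted p values are Benjamini-Hochberg values of the moderated t tests of limma, with 0.05 as the threshold. The dye term passed that threshold for 29 genes. The differences between SRR3413_L3733A and L3733A and between G3745 and L3733A are contrasts of the same model.

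Gene lists, 41 in number, were written before the data were examined and tested with camera at its preset correlation of 0.01, adjusted over the lists of a comparison. The same test with an estimated correlation and the rotation test fry were alternatives. A member counts as risen or fallen by its adjusted p over all genes, and a further count adjusts p over the members of the list only. Genes are named by a rule fixed in advance: per mutant the 10 largest rises and falls among genes past the threshold with the same sign on all 3 arrays, per difference the 5 largest each way past the threshold, TRA1 and PHO5 in every comparison, and 2 to 4 members past the threshold with the largest change for each list that passed or has 3 members past the threshold. The results of 1 list that passed in 3 comparisons and of 2 genes are not reported here, while the counts of genes and lists include them.

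The procedure was tested on simulated data: 200 of 6256 genes were given changes of log2 0.5, 1 or 2. The noise was independent and normal, with the fitted SD of each gene and alike on all arrays. At log2 1 it recovered 94% of them in L3733A, 98.5% in SRR3413_L3733A, 100% in G3745, 83.6% in the difference of SRR3413_L3733A and L3733A, and 88.1% in that of G3745 and L3733A. At log2 0.5 the shares were 56.7%, 50.7%, 61.2%, 10.4% and 13.4%, and at log2 2 they were 100%, 100%, 100%, 95.5% and 100%. False calls numbered 9 of 176, 13 of 179, 9 of 183, 6 of 132 and 7 of 141. The simulated arrays held no correlation within slides (0.197 in the data) or between genes. Nor did any have a wider spread, as array 2 of G3745 has (SD 0.924, against 0.485 on array 1). These shares therefore do not give the error rates of the real calls.

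Alternatives tried were no background correction, the processed signals, the deposited matrix, median centring, kept outlier spots, log ratios scaled between arrays, probe filters, no dye term, a dye term per design or per slide, the 7 arrays of the larger design, array weights, eBayes with trend and robust, slide as a random or fixed block, a replicate block, only the arrays compared, other thresholds and leaving out each array. The correlation of L3733A and SRR3413_L3733A was compared with 100 simulations in which both share reference noise and no gene changes. To compare the 2 wild types, median-centred log2 signals of channels on the same slide and in the same dye were subtracted: CY2706 minus CY3020 in Cy3 on slides 2 and 3, L3733A minus CY3020 in Cy5 on slide 2, SRR3413_L3733A minus CY3020 in Cy3 on slide 3, and G3745 minus CY2706 in Cy3 on slide 2 and Cy5 on slide 3. Channel signals, here and for TRA1, URA3 and the bounds, were taken after loess and quantile scaling of average signal within a design. On slide 2 the Cy3 channel of CY3020 belongs to array 2 of G3745 and the Cy5 channel to array 1. These are single channels and carry no test, except that CY2706 in Cy3 on slide 3 is the mean over arrays 1 and 3 of SRR3413_L3733A, also untested. Genes for the comparison of changes with wild types were taken from slide 1 for L3733A, with the wild types on slide 3, and from slide 3 for SRR3413_L3733A, with the wild types on slide 2.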

Results

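RNA of 3 yeast strains that carry altered plasmid copies of TRA1 was compared with RNA of matched wild-type strains on 9 two-colour arrays, 3 per mutant with 1 dye swap each. TRA1 encodes a subunit shared by the SAGA and NuA4 acetyltransferase complexes, and the series title names its FATC domain. The labels give the alleles by name only, and their further changes are not given in the sources used here. The alleles L3733A and SRR3413_L3733A were measured against wild-type strain CY2706. Strain CY3019, called G3745 here, holds both wild-type TRA1 and the G3745 allele and was measured against CY3020 with wild-type TRA1 on both plasmids. All 6256 genes of the arrays were tested, and 3 arrays per mutant limit the precision of every value. Values are log2 of mutant over reference (n = 3 arrays) with the standard error of the fit. That error rests on the variance of a gene over all 9 arrays, so it is not the spread of 1 mutant's arrays. All genes said to have risen or fallen passed an adjusted p of 0.05. The TRA1 probe does not see point changes, so it checks nothing about the alleles.

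The largest falls in L3733A included several genes of oxidant and drug defence. YDL218W (-4.25 ± 0.38, adjusted p = 0.000285), the aryl-alcohol dehydrogenase gene AAD4 (-4.07 ± 0.30, adjusted p = 0.000144), the NADPH oxidoreductase gene OYE3 (-4.01 ± 0.28, adjusted p = 0.000118) and the drug transporter gene FLR1 (-3.82 ± 0.27, adjusted p = 0.000117) led. The glutathione transferase genes ECM4 (-3.65 ± 0.28) and GTT2 (-3.47 ± 0.22) followed, with OSI1 (-3.55 ± 0.31), the IMP dehydrogenase gene IMD2 (-3.38 ± 0.36), the aldehyde dehydrogenase gene ALD3 (-3.23 ± 0.36) and YML131W (-3.22 ± 0.16). The largest rises were FET3, the multicopper oxidase of iron uptake (2.11 ± 0.19, adjusted p = 0.000277), the CTP synthase gene URA7 (1.82 ± 0.22, adjusted p = 0.000822) and 8 ribosomal protein genes. These were RPL27B (2.09 ± 0.25), RPL3 (1.93 ± 0.22), RPL16A (1.91 ± 0.20), RPS16B (1.89 ± 0.27), RPL5 (1.87 ± 0.23), RPL33B (1.84 ± 0.29), RPS26B (1.77 ± 0.30) and RPL11B (1.75 ± 0.29). PHO5, the secreted acid phosphatase, fell on each of the 3 arrays (-1.42 ± 0.08, adjusted p = 5.48e-05; -1.44, -1.45 and -1.40), while TRA1 itself did not pass (0.05 ± 0.20, adjusted p = 0.881).

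In total 2012 of 6256 genes changed in L3733A, 970 higher and 1042 lower, and 173 and 246 of them by at least 2-fold. Of these, 1998 had the same sign on all 3 arrays, and with the fitted dye term removed all 2012 had it on both slides that hold L3733A arrays. As the genes were called from these same arrays, such agreement is largely built in. It is no independent check, here or in the other mutants below. With slide as a random block 1698 genes passed, without array 2 the count was 558, and with only the 7 arrays of the larger design, 1 of them an L3733A array, it was 0 (1173 at an unadjusted p under 0.05).

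**Figure D1:**
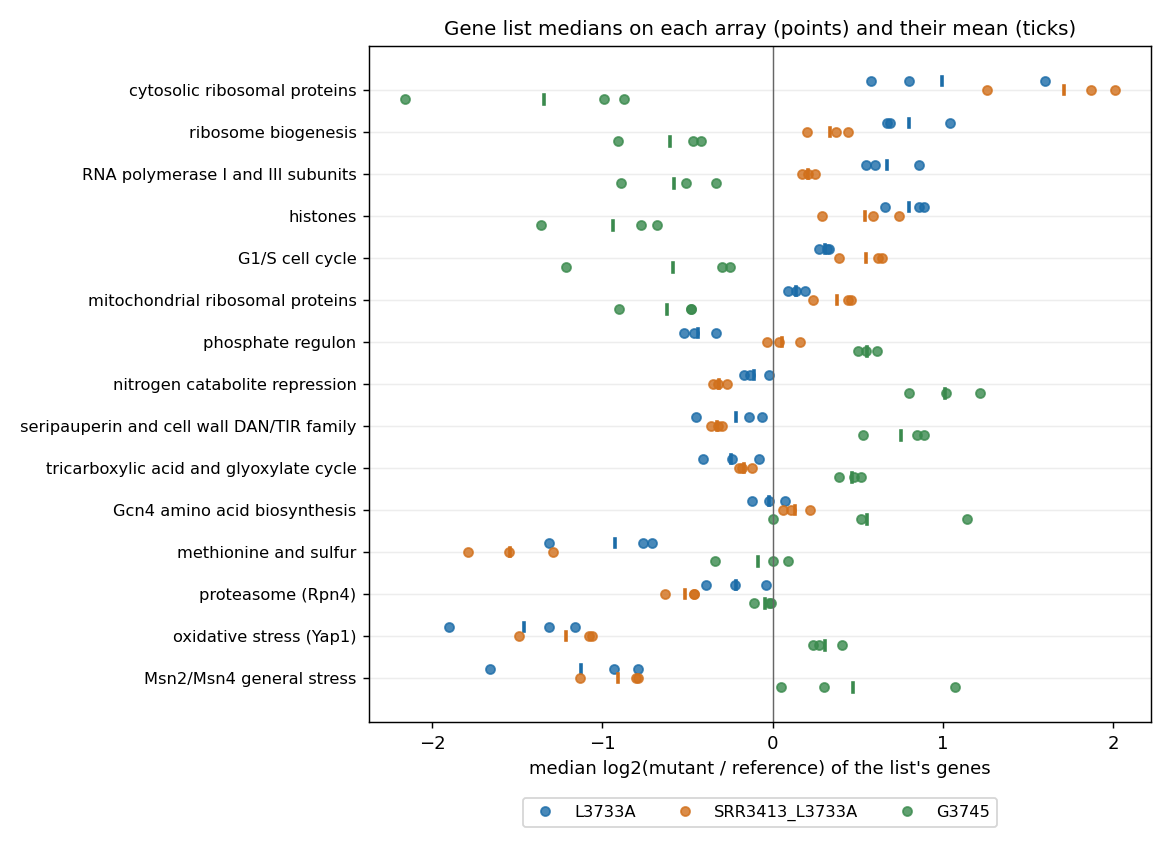
Median log2 of mutant over reference of 15 gene lists, with 1 point per array and a tick at the mean of the 3 arrays of a mutant. Cytosolic ribosomal protein genes lie right of 0 in L3733A (0.80, 1.60 and 0.58) and left of it in G3745 (-0.99, -2.16 and -0.87).

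Genes of ribosome production rose together in L3733A. Beside the ribosomal protein genes these were the processing factors DBP2 (1.68 ± 0.21), NSR1 (1.54 ± 0.18), BRX1 (1.42 ± 0.18) and NOP13 (1.37 ± 0.15) and the RNA polymerase I genes RPA135 (1.17 ± 0.10), RPA49 (1.11 ± 0.15) and RPA43 (1.09 ± 0.12). Histone genes HTB2 (1.55 ± 0.37), HHF2 (1.16 ± 0.28) and HHF1 (1.05 ± 0.23), the ribonucleotide reductase gene RNR1 (1.09 ± 0.36) and the mitotic cyclin gene CLB1 (1.22 ± 0.12) rose as well. Of the 138 cytosolic ribosomal protein genes, 117 rose, 0 fell and 21 did not pass (128 and 0 adjusted over the list alone). Their median was 1.09, camera adjusted p = 1.36e-27, and adjusted p = 0.509 with an estimated correlation. Of the 88 ribosome biogenesis genes, 87 rose, 0 fell and 1 did not pass (87 and 0 adjusted over the list alone). Their median was 0.83, camera adjusted p = 1.3e-32, and adjusted p = 0.318 with an estimated correlation. Of the 19 RNA polymerase I and III subunit genes, 14 rose, 0 fell and 5 did not pass (16 and 0 adjusted over the list alone). Their median was 0.70, camera adjusted p = 1.33e-08, and adjusted p = 0.281 with an estimated correlation. Of the 67 mitochondrial ribosomal protein genes, 13 rose, 1 fell and 53 did not pass (1 and 0 adjusted over the list alone). Their median was 0.17, camera adjusted p = 0.00563, and adjusted p = 0.768 with an estimated correlation. Of the 10 histone genes, 8 rose, 0 fell and 2 did not pass (8 and 0 adjusted over the list alone). Their median was 0.82, camera adjusted p = 0.000528, and adjusted p = 0.509 with an estimated correlation. Of the 35 G1/S genes, 5 rose, 1 fell and 29 did not pass (1 and 0 adjusted over the list alone). Their median was 0.38, camera adjusted p = 0.000494, and adjusted p = 0.752 with an estimated correlation. Of the 20 G2/M genes, 9 rose, 1 fell and 10 did not pass (10 and 1 adjusted over the list alone). Their median was 0.18, camera adjusted p = 0.00511, and adjusted p = 0.279 with an estimated correlation.

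Stress genes, methionine genes and phosphate genes fell in L3733A. Examples are the 6-phosphogluconate dehydrogenase gene GND2 (-3.00 ± 0.31), RTN2 (-2.65 ± 0.28), the thioredoxin gene TRX2 (-2.58 ± 0.25) and the peroxiredoxin gene TSA2 (-2.64 ± 0.25). The heat shock genes SSA4 (-2.22 ± 0.28), HSP30 (-1.76 ± 0.39) and HSP82 (-1.69 ± 0.21) are others. Among sulfur genes the permease MUP3 (-2.99 ± 0.17), the biosynthetic enzyme MET2 (-2.33 ± 0.17) and the sulfate transporter SUL2 (-1.95 ± 0.14) fell, and among phosphate genes SPL2 (-1.47 ± 0.24), PHM7 (-0.92 ± 0.19) and PHM6 (-0.85 ± 0.24). The proteasome regulator RPN4 (-0.79 ± 0.15) and the DNA repair genes PHR1 (-1.27 ± 0.09) and MAG1 (-1.13 ± 0.14) were lower too. Of the 58 Msn2/Msn4 stress genes, 0 rose, 48 fell and 10 did not pass (0 and 53 adjusted over the list alone). Their median was -1.13, camera adjusted p = 2.53e-19, and adjusted p = 0.439 with an estimated correlation. Of the 30 heat shock chaperone genes, 1 rose, 16 fell and 13 did not pass (1 and 19 adjusted over the list alone). Their median was -0.45, camera adjusted p = 3.12e-05, and adjusted p = 0.439 with an estimated correlation. Of the 26 Yap1 oxidative stress genes, 0 rose, 24 fell and 2 did not pass (0 and 25 adjusted over the list alone). Their median was -1.45, camera adjusted p = 3.35e-15, and adjusted p = 0.271 with an estimated correlation. Of the 30 methionine and sulfur genes, 0 rose, 20 fell and 10 did not pass (0 and 22 adjusted over the list alone). Their median was -0.97, camera adjusted p = 5.06e-10, and adjusted p = 0.181 with an estimated correlation. Of the 19 phosphate regulon genes, 0 rose, 9 fell and 10 did not pass (0 and 10 adjusted over the list alone). Their median was -0.47, camera adjusted p = 0.000301, and adjusted p = 0.181 with an estimated correlation. Of the 34 proteasome genes, 0 rose, 12 fell and 22 did not pass (0 and 12 adjusted over the list alone). Their median was -0.24, camera adjusted p = 7.28e-05, and adjusted p = 0.498 with an estimated correlation. Of the 18 DNA damage genes, 0 rose, 6 fell and 12 did not pass (0 and 6 adjusted over the list alone). Their median was -0.21, camera adjusted p = 0.047, and adjusted p = 0.439 with an estimated correlation.

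Lists of carbon metabolism, peroxisome, vitamin, seripauperin and subtelomeric genes shifted in L3733A as well. Among single genes, TDH1 (-1.84 ± 0.24), PYK2 (-1.46 ± 0.11) and GLK1 (-1.10 ± 0.11) of glycolysis fell and HXK2 rose (0.81 ± 0.21). The glyoxylate cycle gene MLS1 (-0.86 ± 0.16), the thiolase gene POT1 (-1.10 ± 0.16, mutant above background on 2 of 3 arrays), the vitamin B6 gene SNZ1 (-1.28 ± 0.24) and the cell wall gene DAN4 (-1.0 ± 0.15) fell, and TIR3 rose (0.71 ± 0.14). Of the 26 tricarboxylic acid and glyoxylate cycle genes, 2 rose, 8 fell and 16 did not pass (2 and 10 adjusted over the list alone). Their median was -0.23, camera adjusted p = 0.0154, and adjusted p = 0.509 with an estimated correlation. Of the 25 glycolysis and ethanol genes, 1 rose, 6 fell and 18 did not pass (1 and 6 adjusted over the list alone). Their median was -0.34, camera adjusted p = 0.0143, and adjusted p = 0.509 with an estimated correlation. Of the 28 fatty acid oxidation and peroxisome genes, 2 rose, 9 fell and 17 did not pass (2 and 11 adjusted over the list alone). Their median was -0.23, camera adjusted p = 0.00378, and adjusted p = 0.521 with an estimated correlation. Of the 27 NAD, thiamine and vitamin B6 genes, 0 rose, 9 fell and 18 did not pass (0 and 9 adjusted over the list alone). Their median was -0.12, camera adjusted p = 0.0406, and adjusted p = 0.477 with an estimated correlation. Of the 30 seripauperin and DAN/TIR genes, 1 rose, 7 fell and 22 did not pass (1 and 7 adjusted over the list alone). Their median was -0.24, camera adjusted p = 0.00185, and adjusted p = 0.509 with an estimated correlation. Of the 366 subtelomeric genes, 19 rose, 73 fell and 274 did not pass (19 and 70 adjusted over the list alone). Their median was -0.08, camera adjusted p = 0.00495, and adjusted p = 0.271 with an estimated correlation. In all, 20 of 41 lists passed in L3733A, 7 up and 13 down. With an estimated correlation 0 passed (6 at an unadjusted p under 0.05). Fry, which tests whether the genes of a list move on balance in 1 direction and does not compare them with other genes, passed 20. The data do not show how far the probes tell apart the near-identical copies of ribosomal protein and seripauperin genes.

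In SRR3413_L3733A ribosomal protein genes held all 10 of the largest rises. Among them were RPL21A (2.63 ± 0.28, adjusted p = 0.000534), RPL9A (2.49 ± 0.38), RPS22A (2.49 ± 0.40), RPS1B (2.44 ± 0.30), RPL24A (2.40 ± 0.32), RPS11A (2.38 ± 0.25), RPS16B (2.33 ± 0.27) and RPS17A (2.32 ± 0.33). The largest falls were SPS100, which encodes a spore wall protein (-4.92 ± 0.31, adjusted p = 8.21e-05), YDL218W (-4.78 ± 0.38, adjusted p = 0.000236), the stress gene GRE1 (-4.05 ± 0.49, adjusted p = 0.000759) and the hexose transporter gene HXT5 (-3.94 ± 0.46, adjusted p = 0.000639). ALD3 (-3.72 ± 0.36), OSI1 (-3.55 ± 0.31), YBR116C (-3.44 ± 0.38), SPG4 (-3.44 ± 0.43), the transketolase gene TKL2 (-3.33 ± 0.33) and AAD4 (-3.28 ± 0.30) followed. PHO5 did not pass (-0.17 ± 0.08, adjusted p = 0.116), and neither did TRA1 (0.42 ± 0.20, adjusted p = 0.125). The TRA1 log2 signals of the mutant were 16, 15.9 and 15.7 on arrays 1 to 3, against 15.5, 15.5 and 15.4 in the reference. Leaving out each array gave TRA1 values of 0.28 to 0.49. As the error pools all 9 arrays, the missed threshold does not show that TRA1 RNA was unchanged.

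A total of 2482 of 6256 genes changed in SRR3413_L3733A, 1225 higher and 1257 lower, and 204 and 237 of them by at least 2-fold. Of these, 2473 had the same sign on all 3 arrays, which share 1 slide. Slide as a random block left 1605 genes, and leaving out array 2 left 814.

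Methionine and sulfate assimilation genes fell by more in this mutant than any other list. SUL2 (-3.26 ± 0.14, adjusted p = 1.92e-05), MET14 (-2.99 ± 0.27), MET3 (-2.94 ± 0.36) and the regulator MET32 (-2.75 ± 0.18) led them. Stress genes GND2 (-3.25 ± 0.31) and NQM1 (-2.88 ± 0.30), the Yap1 targets OYE3 (-3.01 ± 0.28), FLR1 (-2.78 ± 0.27), TRX2 (-2.75 ± 0.25) and SRX1 (-2.71 ± 0.20), and proteasome genes RPN4 (-1.72 ± 0.15), RPN8 (-0.86 ± 0.09) and PUP3 (-0.77 ± 0.10) fell. So did the GABA transaminase gene UGA1 (-1.11 ± 0.11), the amino acid permease gene GAP1 (-0.82 ± 0.16), the peroxisomal catalase gene CTA1 (-1.97 ± 0.11) and DAN4 (-0.85 ± 0.15). Of the 30 methionine and sulfur genes, 1 rose, 24 fell and 5 did not pass (1 and 25 adjusted over the list alone). Their median was -1.57, camera adjusted p = 8.96e-13, and adjusted p = 0.206 with an estimated correlation. Of the 58 Msn2/Msn4 stress genes, 1 rose, 50 fell and 7 did not pass (1 and 52 adjusted over the list alone). Their median was -1.0, camera adjusted p = 2.83e-14, and adjusted p = 0.538 with an estimated correlation. Of the 26 Yap1 oxidative stress genes, 0 rose, 25 fell and 1 did not pass (0 and 25 adjusted over the list alone). Their median was -1.23, camera adjusted p = 3.76e-12, and adjusted p = 0.538 with an estimated correlation. Of the 34 proteasome genes, 0 rose, 28 fell and 6 did not pass (0 and 29 adjusted over the list alone). Their median was -0.51, camera adjusted p = 3.37e-10, and adjusted p = 0.538 with an estimated correlation. Of the 26 nitrogen catabolite repression genes, 1 rose, 11 fell and 14 did not pass (1 and 11 adjusted over the list alone). Their median was -0.29, camera adjusted p = 0.00454, and adjusted p = 0.538 with an estimated correlation. Of the 28 fatty acid oxidation and peroxisome genes, 1 rose, 8 fell and 19 did not pass (1 and 7 adjusted over the list alone). Their median was -0.25, camera adjusted p = 0.0057, and adjusted p = 0.538 with an estimated correlation. Of the 30 seripauperin and DAN/TIR genes, 1 rose, 16 fell and 13 did not pass (1 and 17 adjusted over the list alone). Their median was -0.33, camera adjusted p = 0.000213, and adjusted p = 0.538 with an estimated correlation. Of the 366 subtelomeric genes, 52 rose, 109 fell and 205 did not pass (53 and 111 adjusted over the list alone). Their median was -0.12, camera adjusted p = 0.0354, and adjusted p = 0.538 with an estimated correlation. Of the 40 meiosis and sporulation genes, 1 rose, 7 fell and 32 did not pass (1 and 6 adjusted over the list alone). Their median was -0.14, camera adjusted p = 0.0354, and adjusted p = 0.538 with an estimated correlation.

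Cytosolic and mitochondrial ribosomal proteins, ribosome biogenesis and G1/S genes were among the lists that rose in SRR3413_L3733A. The mitochondrial ribosomal genes MRPL22 (0.76 ± 0.15) and MRPL17 (0.75 ± 0.13), the nucleolar genes NOP56 (0.91 ± 0.19) and NOP1 (0.91 ± 0.15), RPA49 (0.82 ± 0.15), and the S phase genes CDC21 (1.14 ± 0.28), POL30 (1.11 ± 0.33) and RNR1 (1.11 ± 0.36) rose. HTB2 (1.41 ± 0.37), the mannosyltransferase gene PMT2 (1.30 ± 0.27), the translocon gene SEC61 (0.72 ± 0.20) and the sterol genes ERG4 (0.98 ± 0.10) and ERG25 (0.85 ± 0.16) rose too. Of the 138 cytosolic ribosomal protein genes, 133 rose, 0 fell and 5 did not pass (135 and 0 adjusted over the list alone). Their median was 1.84, camera adjusted p = 3.85e-38, and adjusted p = 0.538 with an estimated correlation. Of the 67 mitochondrial ribosomal protein genes, 39 rose, 0 fell and 28 did not pass (48 and 1 adjusted over the list alone). Their median was 0.41, camera adjusted p = 2.79e-09, and adjusted p = 0.538 with an estimated correlation. Of the 88 ribosome biogenesis genes, 48 rose, 1 fell and 39 did not pass (53 and 1 adjusted over the list alone). Their median was 0.39, camera adjusted p = 1.04e-10, and adjusted p = 0.538 with an estimated correlation. Of the 35 G1/S genes, 22 rose, 0 fell and 13 did not pass (27 and 0 adjusted over the list alone). Their median was 0.57, camera adjusted p = 5.23e-07, and adjusted p = 0.538 with an estimated correlation. Of the 26 ergosterol genes, 10 rose, 1 fell and 15 did not pass (10 and 1 adjusted over the list alone). Their median was 0.28, camera adjusted p = 0.00364, and adjusted p = 0.538 with an estimated correlation. Of the 29 unfolded protein response genes, 7 rose, 0 fell and 22 did not pass (4 and 0 adjusted over the list alone). Their median was 0.41, camera adjusted p = 0.0225, and adjusted p = 0.643 with an estimated correlation. Of the 19 RNA polymerase I and III subunit genes, 6 rose, 0 fell and 13 did not pass (6 and 0 adjusted over the list alone). Their median was 0.20, camera adjusted p = 0.0264, and adjusted p = 0.538 with an estimated correlation. Of the 10 histone genes, 3 rose, 0 fell and 7 did not pass (3 and 0 adjusted over the list alone). Their median was 0.58, camera adjusted p = 0.0354, and adjusted p = 0.599 with an estimated correlation.

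Some genes of lists that did not pass still changed in SRR3413_L3733A. FET3 (2.12 ± 0.19), the low-affinity iron transporter gene FET4 (1.29 ± 0.13) and the iron permease gene FTR1 (1.02 ± 0.16) rose, while 8 of 28 iron genes fell (median -0.12, camera adjusted p = 0.613). Among 19 phosphate genes PHO12 (0.87 ± 0.12) rose and PHM7 (-2.13 ± 0.19) and PHM8 (-1.98 ± 0.22) fell (median 0.11, camera adjusted p = 0.717). Camera passed 18 of 41 lists in this mutant, 9 up and 9 down, and fry 25. The estimated correlation passed 0 (3 at an unadjusted p under 0.05).

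**Figure D2:**
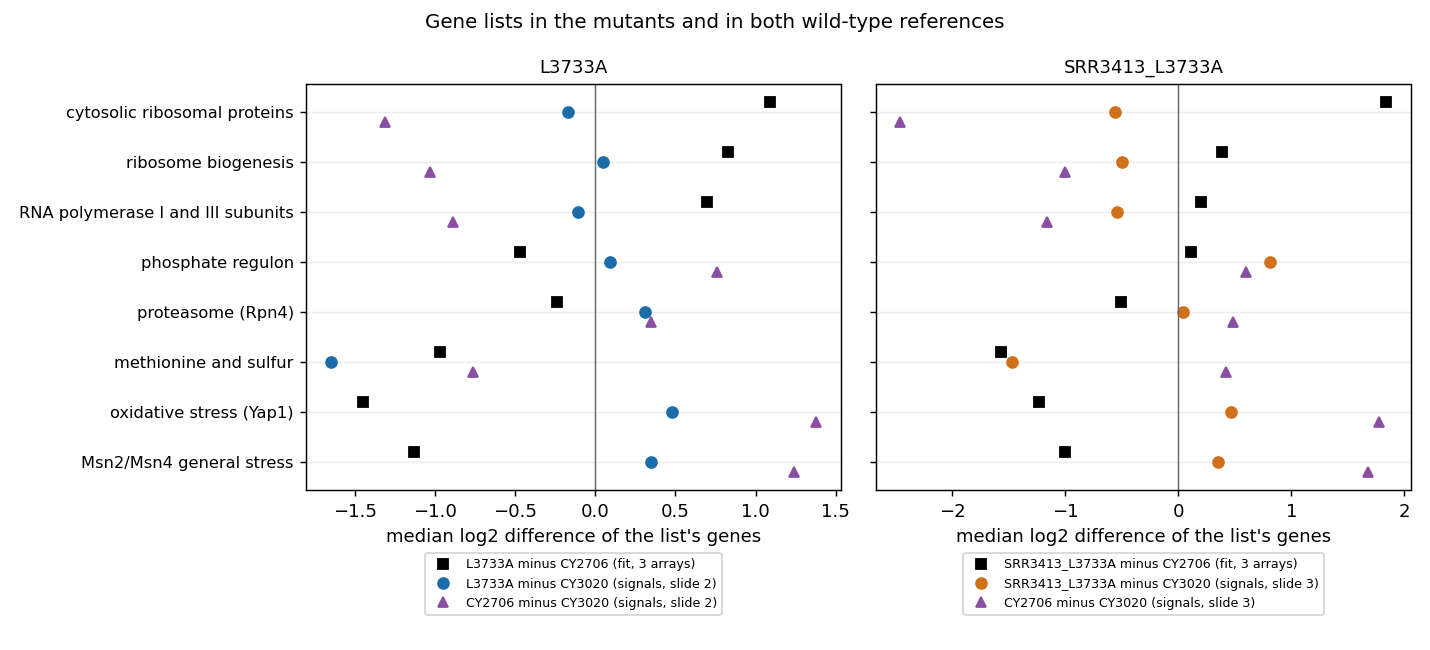
Median log2 of 8 gene lists: squares, fitted mutant over CY2706; circles, the mutant channel minus the CY3020 channel; triangles, the CY2706 channel minus the CY3020 channel, for L3733A on slide 2 and SRR3413_L3733A on slide 3. For cytosolic ribosomal protein genes the triangles lie at -1.31 and -2.46, and the circles at -0.17 and -0.56.

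Many genes that changed in these 2 mutants also differed between the 2 wild-type references. On slide 2 and slide 3, channels of the same dye can be compared directly, with no test. There CY2706 lay below CY3020 for cytosolic ribosomal protein genes (median -1.31 and -2.46) and ribosome biogenesis genes (-1.03 and -1.0). It lay above it for Msn2/Msn4 genes (1.24 and 1.68), Yap1 genes (1.38 and 1.78) and phosphate genes (0.76 and 0.60). To keep the channels that chose the genes out of the comparison, genes with a mean log2 of at least 1 and the same sign on all arrays of 1 slide were compared with the wild types on another slide. Of 443 such L3733A genes from slide 1, 95.7% (424) differed between CY2706 and CY3020 on slide 3 in the direction opposite to their change. Of 420 such SRR3413_L3733A genes from slide 3, 84.5% (355) did so on slide 2, against 50% expected with no relation. On slide 2 this rests on 1 CY3020 channel, that of G3745 array 2, whose log ratios spread more widely (SD 0.924) than those of array 1 (0.485). The labels do not say whether arrays shared reference RNA, which would make these channels less separate. Set against CY3020, ribosomal protein genes stood at -0.17 in L3733A and -0.56 in SRR3413_L3733A, and Msn2/Msn4 genes at 0.35 in each. On slide 2 the L3733A value uses the CY3020 sample of G3745 array 1 and the CY2706 value that of G3745 array 2, so the 2 do not add up to the log ratio of an array. Methionine and sulfur genes stayed low against CY3020 as well (-1.65 in L3733A, -1.47 in SRR3413_L3733A), and FET3 stayed high (3.31 and 3.34). CY2706 itself stood at -0.76 on slide 2 and 0.42 on slide 3 against CY3020 for methionine and sulfur genes, and at 1.46 and 1.52 for FET3. PHO5 was higher in CY2706 than in CY3020 (2.48 and 2.89), and it was higher than in CY3020 by 0.65 in L3733A and by 2.66 in SRR3413_L3733A. The strains also differ in their plasmids, and the data do not say which wild type is the usual state.

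The largest rises in G3745 were the malate synthase gene MLS1 (3.19 ± 0.16, adjusted p = 3.82e-05), the leucine biosynthetic gene LEU1 (3.1 ± 0.40, adjusted p = 0.0018), the decarboxylase gene ARO10 (3.08 ± 0.49, adjusted p = 0.00315), whose reference lay well above background on 2 of 3 arrays, and the phosphate transporter gene PHO84 (2.79 ± 0.28, adjusted p = 0.000697). The biotin genes BIO5 (2.75 ± 0.50), BIO3 (2.65 ± 0.46) and BIO4 (2.39 ± 0.28), the GABA permease gene UGA4 (2.62 ± 0.12, adjusted p = 3.07e-05), the zinc transporter gene ZRT1 (2.56 ± 0.31) and NRS1 (2.49 ± 0.16) followed. The largest falls were the cell wall gene CWP1 (-3.23 ± 0.30, adjusted p = 0.000586), INA1 (-3.15 ± 0.21, adjusted p = 0.000163), the amino acid permease gene TAT1 (-2.72 ± 0.43), MET14 (-2.23 ± 0.27), HTA2 (-2.09 ± 0.40), YOL014W (-2.64 ± 0.29) and COS12 (-2.06 ± 0.14), both above background in the mutant on 2 of 3 arrays, and the ribosomal protein genes RPL9A (-2.59 ± 0.38), RPS22A (-2.11 ± 0.40) and RPS22B (-2.09 ± 0.33). PHO5 rose on all 3 arrays (1.93, 1.71 and 1.78; 1.82 ± 0.08, adjusted p = 2.44e-05). TRA1 did not pass (0.33 ± 0.20, adjusted p = 0.202), with 1.11 on array 2 against 0.04 and -0.06 on the others.

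In this comparison 2864 of 6256 genes changed, 1464 higher and 1400 lower, and 193 and 254 by at least 2-fold. A fit of the 3 G3745 arrays alone, with its own variance and no dye term, passed 23 genes, 19 higher and 4 lower. Of the 2864, 2836 had the same sign on all 3 arrays, and with the fitted dye term removed 2833 (98.9%) had it on slide 3. Slide as a random block left 2467, and leaving out array 1 left 723. Set against CY2706 as single channels with no test, on slides 2 and 3, G3745 stood at -0.75 and -1.62 for Msn2/Msn4 genes, 0.03 and -0.22 for phosphate genes, -0.13 and -1.03 for PHO5 and -0.31 and 1.64 for cytosolic ribosomal protein genes. Nitrogen catabolite repression genes (1.31 and 0.62) stood above CY2706 as well as CY3020. Gcn4 genes stood above CY2706 too (1.03 and 0.42). They stood above CY3020 on the slide 2 arrays (0.52 and 1.14) but not on the slide 3 array (0.00). SPO19 of the spore list lay below background in both channels on all 3 arrays and is given no fold. The actin gene ACT1 of the NuA4 list rose (0.42 ± 0.10) but stood at -0.01 with median centring.

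**Figure D3:**
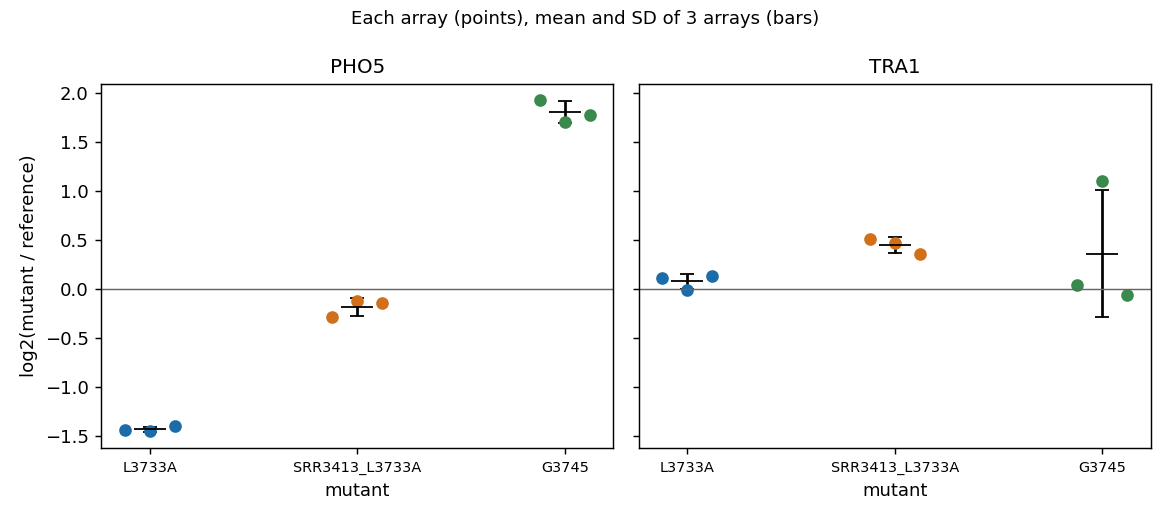
Log2 of mutant over reference for PHO5 and TRA1 on each array (points), with the mean and SD of the 3 arrays of each mutant. PHO5 lies near -1.42 in L3733A and 1.82 in G3745, and the TRA1 points of G3745 spread from -0.06 to 1.11.

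Nutrient supply lists rose in G3745. They include the phosphate genes GIT1 (2.32 ± 0.39) and SPL2 (1.40 ± 0.24), and the nitrogen genes DAL5 (2.30 ± 0.28), DAL80 (1.92 ± 0.13) and PUT1 (1.84 ± 0.13). LEU4 (2.13 ± 0.39), ILV2 (2.05 ± 0.36) and BAT1 (1.85 ± 0.34) of branched-chain amino acid synthesis rose, with the carbon genes CIT3 (2.13 ± 0.14), PYC1 (1.87 ± 0.12), YAT1 (2.03 ± 0.08) and POX1 (1.47 ± 0.20). The heme oxygenase gene HMX1 (2.38 ± 0.16) and the biotin transporter gene VHT1 (1.83 ± 0.46) of the iron list, and BNA2 (2.15 ± 0.15) and SNZ1 (1.77 ± 0.24) of NAD and vitamin B6 synthesis were also higher. Of the 19 phosphate regulon genes, 10 rose, 0 fell and 9 did not pass (12 and 0 adjusted over the list alone). Their median was 0.58, camera adjusted p = 0.000182, and adjusted p = 0.165 with an estimated correlation. Of the 26 nitrogen catabolite repression genes, 23 rose, 0 fell and 3 did not pass (25 and 0 adjusted over the list alone). Their median was 0.86, camera adjusted p = 8.36e-11, and adjusted p = 0.168 with an estimated correlation. Of the 65 Gcn4 amino acid biosynthesis genes, 27 rose, 7 fell and 31 did not pass (34 and 7 adjusted over the list alone). Their median was 0.61, camera adjusted p = 0.000222, and adjusted p = 0.64 with an estimated correlation. Of the 26 tricarboxylic acid and glyoxylate cycle genes, 15 rose, 1 fell and 10 did not pass (15 and 1 adjusted over the list alone). Their median was 0.53, camera adjusted p = 0.000303, and adjusted p = 0.413 with an estimated correlation. Of the 28 fatty acid oxidation and peroxisome genes, 18 rose, 2 fell and 8 did not pass (19 and 2 adjusted over the list alone). Their median was 0.59, camera adjusted p = 1.5e-05, and adjusted p = 0.413 with an estimated correlation. Of the 28 iron (Aft1) genes, 16 rose, 0 fell and 12 did not pass (17 and 0 adjusted over the list alone). Their median was 0.42, camera adjusted p = 0.00055, and adjusted p = 0.413 with an estimated correlation. Of the 27 NAD, thiamine and vitamin B6 genes, 17 rose, 2 fell and 8 did not pass (20 and 2 adjusted over the list alone). Their median was 0.46, camera adjusted p = 0.000228, and adjusted p = 0.282 with an estimated correlation. Gcn4 genes stood at 0.52, 1.14 and 0.00 on arrays 1 to 3, and nitrogen genes at 1.02, 1.22 and 0.80.

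Other rising lists in G3745 were those of Msn2/Msn4 stress, multidrug resistance, DNA damage, seripauperin, flocculation and subtelomeric genes, while heat shock (median 0.27, camera adjusted p = 0.152) and Yap1 genes (0.23, camera adjusted p = 0.185) did not pass. The catalase gene CTT1 (1.85 ± 0.37), DDR2 (1.70 ± 0.31) and HSP26 (1.53 ± 0.42), the transporter genes PDR12 (1.63 ± 0.27) and PDR10 (1.28 ± 0.14), the ubiquitin gene UBI4 (1.04 ± 0.12), the seripauperin genes PAU22 (1.21 ± 0.15) and PAU21 (1.20 ± 0.15), and FLO1 (0.92 ± 0.12) and FLO10 (0.86 ± 0.15) rose. Of the 58 Msn2/Msn4 stress genes, 23 rose, 0 fell and 35 did not pass (20 and 0 adjusted over the list alone). Their median was 0.34, camera adjusted p = 0.000232, and adjusted p = 0.661 with an estimated correlation. Of the 19 multidrug resistance genes, 9 rose, 0 fell and 10 did not pass (9 and 0 adjusted over the list alone). Their median was 0.50, camera adjusted p = 0.00113, and adjusted p = 0.413 with an estimated correlation. Of the 18 DNA damage genes, 8 rose, 1 fell and 9 did not pass (8 and 1 adjusted over the list alone). Their median was 0.15, camera adjusted p = 0.0497, and adjusted p = 0.413 with an estimated correlation. Of the 30 seripauperin and DAN/TIR genes, 26 rose, 2 fell and 2 did not pass (26 and 2 adjusted over the list alone). Their median was 0.69, camera adjusted p = 1.42e-08, and adjusted p = 0.413 with an estimated correlation. Of the 15 flocculation and filament genes, 6 rose, 0 fell and 9 did not pass (5 and 0 adjusted over the list alone). Their median was 0.25, camera adjusted p = 0.0249, and adjusted p = 0.476 with an estimated correlation. Of the 366 subtelomeric genes, 152 rose, 39 fell and 175 did not pass (152 and 41 adjusted over the list alone). Their median was 0.19, camera adjusted p = 8.33e-05, and adjusted p = 0.165 with an estimated correlation. The Msn2/Msn4 medians were 0.30, 1.07 and 0.05 on arrays 1 to 3.

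Ribosome, histone and G1/S lists fell in G3745. Examples are RPS18A (-2.06 ± 0.32), the mitochondrial ribosomal genes RSM26 (-1.52 ± 0.15) and MRPL20 (-1.31 ± 0.23), the ribosome assembly genes NIP7 (-1.95 ± 0.27) and UTP11 (-1.32 ± 0.13), and the polymerase genes RPA34 (-1.64 ± 0.20) and RPC25 (-1.15 ± 0.20). HTB2 (-1.69 ± 0.37), HHF2 (-1.39 ± 0.28), RNR1 (-1.44 ± 0.36) and POL30 (-1.27 ± 0.33) fell. Of the 138 cytosolic ribosomal protein genes, 0 rose, 135 fell and 3 did not pass (0 and 137 adjusted over the list alone). Their median was -1.26, camera adjusted p = 1.22e-27, and adjusted p = 0.413 with an estimated correlation. Of the 67 mitochondrial ribosomal protein genes, 0 rose, 58 fell and 9 did not pass (0 and 59 adjusted over the list alone). Their median was -0.61, camera adjusted p = 2.21e-14, and adjusted p = 0.413 with an estimated correlation. Of the 88 ribosome biogenesis genes, 0 rose, 70 fell and 18 did not pass (0 and 72 adjusted over the list alone). Their median was -0.57, camera adjusted p = 2.72e-17, and adjusted p = 0.413 with an estimated correlation. Of the 19 RNA polymerase I and III subunit genes, 0 rose, 13 fell and 6 did not pass (0 and 13 adjusted over the list alone). Their median was -0.52, camera adjusted p = 4.44e-05, and adjusted p = 0.413 with an estimated correlation. Of the 10 histone genes, 0 rose, 9 fell and 1 did not pass (0 and 10 adjusted over the list alone). Their median was -0.87, camera adjusted p = 8.33e-05, and adjusted p = 0.451 with an estimated correlation. Of the 35 G1/S genes, 0 rose, 20 fell and 15 did not pass (0 and 21 adjusted over the list alone). Their median was -0.53, camera adjusted p = 1.71e-05, and adjusted p = 0.599 with an estimated correlation. G1/S genes stood at -0.30, -1.21 and -0.25 on arrays 1 to 3. Camera passed 20 of 41 lists in G3745, 13 up and 7 down, and fry 24, while an estimated correlation passed 0 (4 at an unadjusted p under 0.05).

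Between SRR3413_L3733A and L3733A the largest differences were in single genes of varied function. IMD2 (3.35 ± 0.50, adjusted p = 0.00582), the purine synthesis gene ADE17 (3.18 ± 0.42, adjusted p = 0.00406), the pyruvate kinase gene PYK2 (2.17 ± 0.15, adjusted p = 0.00105), RTC2 (2.17 ± 0.63, adjusted p = 0.0497) and EMI2 (2.16 ± 0.14, adjusted p = 0.000912) were higher in SRR3413_L3733A, as was PHO5 (1.25 ± 0.11, adjusted p = 0.00107). GRE1 (-3.04 ± 0.68, adjusted p = 0.0215), HXT5 (-2.81 ± 0.63, adjusted p = 0.0219), the permease gene SEO1 (-2.42 ± 0.40, adjusted p = 0.00831), YBR116C (-2.40 ± 0.53, adjusted p = 0.0206) and YKL070W (-2.15 ± 0.17, adjusted p = 0.00106) were lower. MLS1 was lower too (-1.02 ± 0.22) but stood at 0.08 with processed signals, and TRA1 did not pass (0.37 ± 0.27, adjusted p = 0.386). Together 1061 of 6256 genes differed, 517 higher and 544 lower, and 114 and 88 by at least 2-fold. No slide holds both mutants: 600 genes passed with slide as a random block, and 1 with slide as a fixed block, which links the mutants only through G3745 arrays. CY2706 minus CY3020, as single channels with no test, was -1.43 on slide 2 and 3.2 on slide 3 for GRE1. It was 1.45 and 4.8 for HXT5, -1.28 and 1.05 for SEO1, 1.41 and 4.25 for YBR116C, and 1.15 and 3.78 for YKL070W. For IMD2 (2.41 and 2.22) and EMI2 (0.44 and 0.5) it moved less. For ADE17 (0.93 and -0.26), PYK2 (0.9 and 0.3) and RTC2 (-0.48 and -1.57) it fell. Differences between these mutants can therefore hold a change of reference between slides. The 7 arrays of the larger design passed 0 genes (1049 at an unadjusted p under 0.05), and leaving out SRR3413_L3733A array 2 left 204.

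Phosphate and ribosomal lists had higher log ratios over CY2706, and biogenesis, methionine and proteasome lists lower ones, in SRR3413_L3733A than in L3733A. PHO12 (1.34 ± 0.16), RPS17A (1.60 ± 0.45), RPS8A (1.57 ± 0.39), MRPL17 (0.85 ± 0.17) and the endoplasmic reticulum gene CPR5 (0.91 ± 0.19) were higher. NSR1 (-1.30 ± 0.25), RLP7 (-0.97 ± 0.16), RPO31 (-0.82 ± 0.14), MET5 (-1.59 ± 0.23), MET32 (-1.56 ± 0.24), RPN4 (-0.93 ± 0.21) and PHM8 (-1.29 ± 0.30) were lower. Of the 19 phosphate regulon genes, 5 were higher, 2 were lower and 12 did not pass (9 and 2 adjusted over the list alone). Their median was 0.44, camera adjusted p = 0.00155, and adjusted p = 0.439 with an estimated correlation. Of the 138 cytosolic ribosomal protein genes, 14 were higher, 2 were lower and 122 did not pass (0 and 1 adjusted over the list alone). Their median was 0.74, camera adjusted p = 1.26e-07, and adjusted p = 0.803 with an estimated correlation. With slide as a fixed block the ribosomal protein median was -0.21 and passed in the opposite direction (camera adjusted p = 0.015). Of the 67 mitochondrial ribosomal protein genes, 5 were higher, 1 were lower and 61 did not pass (2 and 0 adjusted over the list alone). Their median was 0.24, camera adjusted p = 0.00147, and adjusted p = 0.803 with an estimated correlation. Of the 88 ribosome biogenesis genes, 0 were higher, 20 were lower and 68 did not pass (0 and 35 adjusted over the list alone). Their median was -0.44, camera adjusted p = 4.82e-13, and adjusted p = 0.803 with an estimated correlation. Of the 19 RNA polymerase I and III subunit genes, 0 were higher, 3 were lower and 16 did not pass (0 and 4 adjusted over the list alone). Their median was -0.43, camera adjusted p = 0.000352, and adjusted p = 0.803 with an estimated correlation. Of the 29 unfolded protein response genes, 3 were higher, 0 were lower and 26 did not pass (3 and 0 adjusted over the list alone). Their median was 0.39, camera adjusted p = 0.0252, and adjusted p = 0.803 with an estimated correlation. That median was -0.87 with slide as a fixed block and also passed in the opposite direction (camera adjusted p = 3.51e-05). Of the 30 methionine and sulfur genes, 2 were higher, 8 were lower and 20 did not pass (2 and 10 adjusted over the list alone). Their median was -0.46, camera adjusted p = 0.000751, and adjusted p = 0.803 with an estimated correlation. Of the 34 proteasome genes, 0 were higher, 2 were lower and 32 did not pass (0 and 2 adjusted over the list alone). Their median was -0.26, camera adjusted p = 0.000614, and adjusted p = 0.803 with an estimated correlation. Fry passed 1 of 41 lists against 8 with camera, 4 in each direction, and an estimated correlation passed 0 (1 at an unadjusted p under 0.05). Against CY3020, as untested single channels, L3733A and SRR3413_L3733A had the other order for cytosolic ribosomal proteins (-0.17 and -0.56). So they had for mitochondrial ribosomal proteins (0.33 and 0) and methionine and sulfur (-1.65 and -1.47). Phosphate (0.09 and 0.81), ribosome biogenesis (0.05 and -0.5) and RNA polymerase lists (-0.11 and -0.54) kept their order. Unfolded protein response (-0.78 and 0.25) and proteasome lists (0.31 and 0.04) kept it too.

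The log ratio of G3745 over CY3020 was opposite in sign to that of L3733A over CY2706 for most genes that changed in both (951 against 150 alike). The defence genes OYE3 (4.57 ± 0.39, adjusted p = 0.000203), GTT2 (4.39 ± 0.31), ECM4 (4.30 ± 0.38) and FLR1 (4.30 ± 0.37), the vacuolar peptidase gene APE1 (4.42 ± 0.38) and PHO5 (3.24 ± 0.11, adjusted p = 6.43e-06) had the higher log ratio in G3745. INA1 (-4.52 ± 0.29, adjusted p = 0.000104), CWP1 (-4.30 ± 0.41), RPL9A (-3.78 ± 0.53), RPS16B (-3.66 ± 0.37), RPL27B (-3.65 ± 0.34) and FET3 (-2.35 ± 0.26) had the lower, and TRA1 did not pass (0.28 ± 0.27, adjusted p = 0.417). In all 3206 of 6256 genes differed, 1698 higher and 1508 lower, and 668 and 629 by at least 2-fold. Slide 2 holds arrays of both mutants, and with slide as a fixed block 2651 genes passed. ACT1 (0.47 ± 0.14) stood at -0.02 with median centring. As each mutant has its own wild type, these are differences of ratios, not of levels, and include any between CY2706 and CY3020. Against CY3020 on slide 2, L3733A itself stood at 2.46 for OYE3, 3.04 for GTT2, 1.32 for ECM4 and 1.80 for FLR1, at 0.35 for Msn2/Msn4 genes and at 0.48 for Yap1 genes, while the fitted G3745 medians of these lists were 0.34 and 0.23. A single channel is set here against ratios of 3 arrays. Yap1 genes were not higher in G3745 by this measure (0.27, 0.41 and 0.24 on its arrays). Msn2/Msn4 genes cannot be ordered: L3733A stood at 0.30 with processed signals, and G3745 arrays 1 to 3 at 0.30, 1.07 and 0.05. The measure does not level every list. Nitrogen catabolite repression genes stood at -0.50 in L3733A against CY3020 and at 1.02, 1.22 and 0.80 on the G3745 arrays.

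Stress, phosphate, nitrogen, peroxisome, carbon and methionine lists had the higher log ratios in G3745, each mutant over its own wild type. CTT1 (3.98 ± 0.52), GND2 (3.89 ± 0.43), the lactate dehydrogenase gene CYB2 (4.22 ± 0.24), MLS1 (4.05 ± 0.22), PHO84 (3.47 ± 0.38), SPL2 (2.86 ± 0.33) and UGA4 (2.33 ± 0.17) are examples. Of the 58 Msn2/Msn4 stress genes, 51 had a higher log ratio, 0 a lower log ratio and 7 did not pass (53 and 0 adjusted over the list alone). Their median was 1.51, camera adjusted p = 1.68e-13, and adjusted p = 0.395 with an estimated correlation. Of the 26 Yap1 oxidative stress genes, 23 had a higher log ratio, 0 a lower log ratio and 3 did not pass (24 and 0 adjusted over the list alone). Their median was 1.39, camera adjusted p = 9.9e-09, and adjusted p = 0.35 with an estimated correlation. Of the 19 phosphate regulon genes, 15 had a higher log ratio, 0 a lower log ratio and 4 did not pass (16 and 0 adjusted over the list alone). Their median was 1.14, camera adjusted p = 1.74e-05, and adjusted p = 0.112 with an estimated correlation. Of the 26 nitrogen catabolite repression genes, 20 had a higher log ratio, 0 a lower log ratio and 6 did not pass (23 and 0 adjusted over the list alone). Their median was 1.05, camera adjusted p = 1.14e-07, and adjusted p = 0.324 with an estimated correlation. Of the 28 fatty acid oxidation and peroxisome genes, 19 had a higher log ratio, 2 a lower log ratio and 7 did not pass (21 and 2 adjusted over the list alone). Their median was 0.96, camera adjusted p = 7.96e-06, and adjusted p = 0.395 with an estimated correlation. Of the 26 tricarboxylic acid and glyoxylate cycle genes, 17 had a higher log ratio, 2 a lower log ratio and 7 did not pass (17 and 2 adjusted over the list alone). Their median was 0.93, camera adjusted p = 0.000521, and adjusted p = 0.395 with an estimated correlation. Of the 30 methionine and sulfur genes, 17 had a higher log ratio, 3 a lower log ratio and 10 did not pass (17 and 4 adjusted over the list alone). Their median was 0.91, camera adjusted p = 0.00935, and adjusted p = 0.395 with an estimated correlation. Of the 30 heat shock chaperone genes, 18 had a higher log ratio, 3 a lower log ratio and 9 did not pass (19 and 3 adjusted over the list alone). Their median was 0.74, camera adjusted p = 0.00167, and adjusted p = 0.41 with an estimated correlation.

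A further 6 lists had higher log ratios in G3745. Of the 65 Gcn4 amino acid biosynthesis genes, 23 had a higher log ratio, 5 a lower log ratio and 37 did not pass (21 and 5 adjusted over the list alone). Their median was 0.67, camera adjusted p = 0.00935, and adjusted p = 0.666 with an estimated correlation. Of the 19 multidrug resistance genes, 14 had a higher log ratio, 1 a lower log ratio and 4 did not pass (14 and 1 adjusted over the list alone). Their median was 0.74, camera adjusted p = 0.00297, and adjusted p = 0.395 with an estimated correlation. Of the 18 DNA damage genes, 10 had a higher log ratio, 1 a lower log ratio and 7 did not pass (11 and 1 adjusted over the list alone). Their median was 0.46, camera adjusted p = 0.0183, and adjusted p = 0.35 with an estimated correlation. Of the 27 NAD, thiamine and vitamin B6 genes, 15 had a higher log ratio, 2 a lower log ratio and 10 did not pass (17 and 2 adjusted over the list alone). Their median was 0.54, camera adjusted p = 0.000405, and adjusted p = 0.324 with an estimated correlation. Of the 30 seripauperin and DAN/TIR genes, 24 had a higher log ratio, 1 a lower log ratio and 5 did not pass (27 and 2 adjusted over the list alone). Their median was 0.91, camera adjusted p = 2.77e-07, and adjusted p = 0.395 with an estimated correlation. Of the 366 subtelomeric genes, 154 had a higher log ratio, 28 a lower log ratio and 184 did not pass (154 and 28 adjusted over the list alone). Their median was 0.34, camera adjusted p = 9.82e-06, and adjusted p = 0.112 with an estimated correlation. Genes of the ribosome biogenesis and histone lists had lower log ratios, with NIP7 (-3.02 ± 0.37) and HTB2 (-3.24 ± 0.51) as examples.

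Ribosome, histone and G1/S lists were among the 7 with lower log ratios in G3745 than in L3733A. Of the 138 cytosolic ribosomal protein genes, 0 had a higher log ratio, 136 a lower log ratio and 2 did not pass (0 and 137 adjusted over the list alone). Their median was -2.35, camera adjusted p = 3.52e-33, and adjusted p = 0.395 with an estimated correlation. Of the 88 ribosome biogenesis genes, 0 had a higher log ratio, 88 a lower log ratio and 0 did not pass (0 and 88 adjusted over the list alone). Their median was -1.39, camera adjusted p = 2.61e-29, and adjusted p = 0.35 with an estimated correlation. Of the 19 RNA polymerase I and III subunit genes, 0 had a higher log ratio, 19 a lower log ratio and 0 did not pass (0 and 19 adjusted over the list alone). Their median was -1.25, camera adjusted p = 1.58e-08, and adjusted p = 0.342 with an estimated correlation. Of the 67 mitochondrial ribosomal protein genes, 1 had a higher log ratio, 55 a lower log ratio and 11 did not pass (1 and 57 adjusted over the list alone). Their median was -0.75, camera adjusted p = 5.67e-12, and adjusted p = 0.395 with an estimated correlation. Of the 10 histone genes, 0 had a higher log ratio, 9 a lower log ratio and 1 did not pass (0 and 9 adjusted over the list alone). Their median was -1.74, camera adjusted p = 2.5e-05, and adjusted p = 0.395 with an estimated correlation. Of the 35 G1/S genes, 1 had a higher log ratio, 25 a lower log ratio and 9 did not pass (1 and 25 adjusted over the list alone). Their median was -0.95, camera adjusted p = 1.19e-06, and adjusted p = 0.502 with an estimated correlation. Camera passed 21 of 41 lists, 14 up and 7 down, fry 31, and an estimated correlation 0 (5 at an unadjusted p under 0.05).

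**Figure D4:**
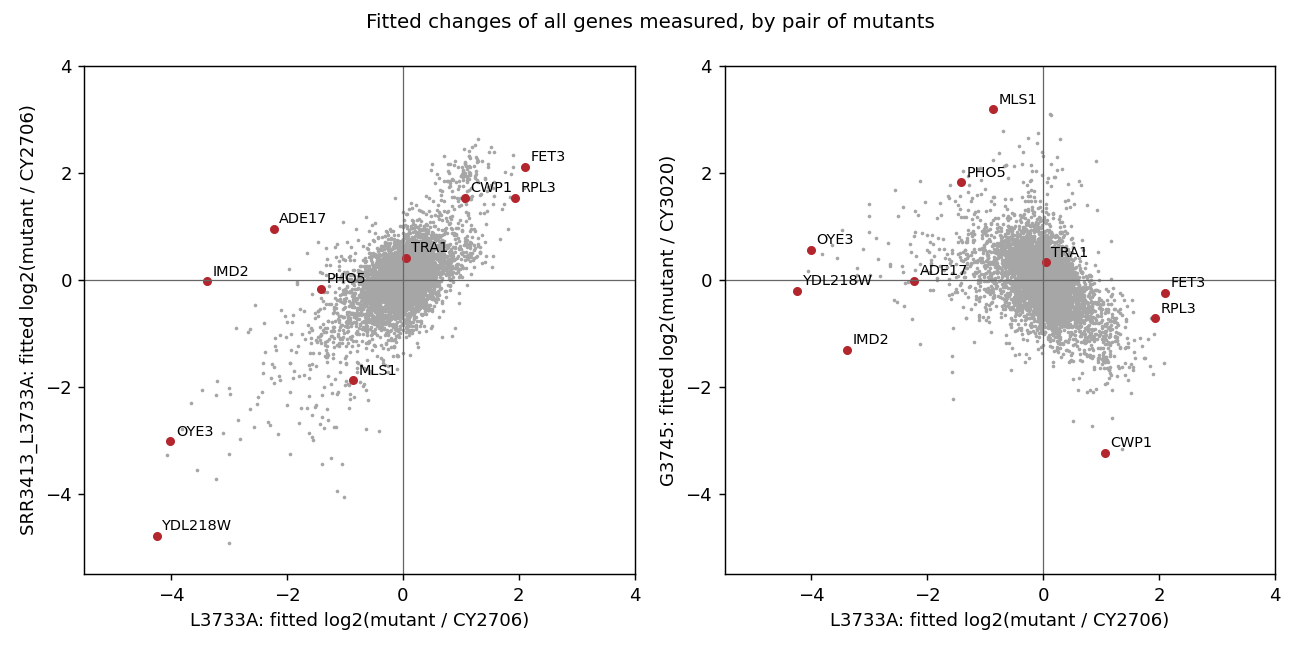
Fitted log2 of mutant over reference of 6256 genes, L3733A on the horizontal axis against SRR3413_L3733A and against G3745, with labelled genes of the text. The correlation is 0.661 in one panel and -0.444 in the other.

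Across the 6256 genes L3733A and SRR3413_L3733A correlated at 0.661, and each correlated negatively with G3745 (-0.444 and -0.528). Genes changed alike in L3733A and SRR3413_L3733A numbered 465 higher (190 expected from the list sizes) and 512 lower (209 expected), against 142 changed in opposite directions. Those expected counts treat the mutants as independent. Simulated data with shared reference noise and no effect gave 0 shared calls, but with no changed gene few calls could arise in any case. L3733A and G3745 shared 150 genes changed alike and 951 changed oppositely, 524 higher in L3733A and lower in G3745 (217 expected) and 427 the other way (244 expected). SRR3413_L3733A and G3745 shared 146 alike and 1232 oppositely (631 and 601, with 274 and 294 expected). A reference shared by 2 mutants gives a correlation by itself: simulated data with no effect gave 0.524 for L3733A and SRR3413_L3733A, with a covariance of 0.0111 against 0.2101 measured. The share of genes with the same sign was 66.9% measured and 67.7% simulated. That simulation assumes that arrays of equal number in the 2 mutants share the noise of 1 reference RNA, which the labels do not state. It holds no lasting difference between CY2706 and the mutants. Its calls and covariance therefore cannot tell a state of the reference from an effect of the alleles. With the fitted dye term removed, on slide 2 alone L3733A and G3745 correlated at -0.42, and on slide 3 SRR3413_L3733A and G3745 at -0.25.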

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

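Of the tests in this part, those of the reference state, of processed signals for the opposite sign and of array 2 of G3745 were chosen only after the result was seen. The genes and lists of the next 2 paragraphs drew attention because a test found a difference between mutants, and the 3 patterns after them were chosen on reading the values. Groups of 3 arrays were not tested for stray samples.

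Between SRR3413_L3733A and L3733A the tested differences were IMD2 3.35, ADE17 3.18, PYK2 2.17, RTC2 2.17, EMI2 2.16, PHO5 1.25, GRE1 -3.04, HXT5 -2.81, SEO1 -2.42, YBR116C -2.40 and YKL070W -2.15. As single channels, CY2706 minus CY3020 rose from slide 2 to slide 3 for each of the lower genes (-1.43 to 3.2 for GRE1). It did not for IMD2 (2.41 to 2.22). The list medians that differed were phosphate regulon 0.44, cytosolic ribosomal proteins 0.74, mitochondrial ribosomal proteins 0.24, ribosome biogenesis -0.44, RNA polymerase I and III subunits -0.43, unfolded protein response 0.39, methionine and sulfur -0.46 and proteasome -0.26. These list calls rest on camera at its preset correlation: with an estimated correlation 0 of 41 passed, and fry passed 1. Against CY3020, as single channels, L3733A and SRR3413_L3733A had the other order for cytosolic ribosomal proteins (-0.17 and -0.56). So they had for mitochondrial ribosomal proteins (0.33 and 0) and methionine and sulfur (-1.65 and -1.47). With slide as a fixed block the ribosomal protein median (-0.21) and the unfolded protein response median (-0.87) passed in the opposite direction (camera adjusted p = 0.015 and 3.51e-05).

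Between G3745 and L3733A they were OYE3 4.57, APE1 4.42, GTT2 4.39, ECM4 4.30, FLR1 4.30, PHO5 3.24, INA1 -4.52, CWP1 -4.30, RPL9A -3.78, RPS16B -3.66 and RPL27B -3.65. These are differences between ratios to 2 wild types. Against CY3020 alone, as a single channel, L3733A stood at 0.48 for Yap1 genes, not below the fitted G3745 median of 0.23. For Msn2/Msn4 genes L3733A stood at 0.35 (0.30 with processed signals) and the fitted G3745 median at 0.34. G3745 arrays 1 to 3 stood at 0.30, 1.07 and 0.05 for that list, so no order can be told. Lists with a higher median log ratio in G3745 were phosphate regulon 1.14, Msn2/Msn4 stress 1.51, heat shock 0.74, Gcn4 0.67, methionine and sulfur 0.91, tricarboxylic acid and glyoxylate cycle 0.93, multidrug resistance 0.74, Yap1 1.39, DNA damage 0.46, nitrogen catabolite repression 1.05, fatty acid oxidation and peroxisome 0.96, NAD, thiamine and vitamin B6 0.54, seripauperin 0.91 and subtelomeric 0.34. Lower ones were cytosolic ribosomal proteins -2.35, mitochondrial ribosomal proteins -0.75, ribosome biogenesis -1.39, RNA polymerase I and III subunits -1.25, histones -1.74 and G1/S -0.95. An estimated correlation passed 0 of these lists, and fry passed 31 of 41.

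Ribosomal protein genes rose and stress genes fell in both L3733A and SRR3413_L3733A, which share CY2706 as reference. If the state of the CY2706 cultures made these changes, CY2706 should differ from CY3020 in the opposite direction for over 80 percent of changed genes chosen on another slide, and the lower share of the 2 mutants was 84.5%, against 50% with no relation. This bar was set after related values were seen. For the 977 genes changed alike in both mutants, CY2706 minus CY3020 had a slope of -1.01 on the L3733A change (slide 2). On the SRR3413_L3733A change it was -1.24 (slide 3). CY2706 lies on both sides of these slopes, which by itself pulls them below 0. The mutants minus CY3020 had slopes of -0.12 (L3733A) and -0.16 (SRR3413_L3733A). As a change is the mutant minus CY2706, these largely restate the slopes before and are no second observation. These channels also took part in choosing the genes, and the slopes carry no test. They leave open that most of the shared pattern could reflect the reference rather than the alleles. If loess made the changes, the ribosomal protein median should fall under 0.2 with processed signals or median centring. The lowest was 1.13, which argues against loess. Methionine and sulfur genes and FET3 kept their direction against CY3020 (-1.65 and 3.31 in L3733A, with CY2706 at -0.76 and 1.46 on the same slide), and the 2 wild types also differ in plasmids.

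G3745 changed opposite in sign to L3733A. If a difference between the wild types along the same axis accounted for it, the correlation of L3733A on slide 1 and G3745 on slide 2 (-0.505) should come near 0 given CY2706 minus CY3020 on slide 3, and it came to -0.064, a value that could arise if both mutants move between the states of their references. If the loess and background correction used here made the sign, processed signals should give a correlation above -0.1. They gave -0.392, which argues against these steps. Over the alternatives other than leaving out arrays, median centring among them, the correlation lay between -0.457 and -0.361. No biological explanation was tested.

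Log ratios of G3745 were larger on array 2 (SD 0.924) than on array 1 (0.485). A single gain on that array should give all lists the same slope, and the slopes of ribosomal protein genes (2.21) and nitrogen genes (0.94) had a ratio of 2.35, which argues against it. The dye should act alike on array 3, with the mutant in the same dye, and its SD was 0.476, which argues against it too. A different state of that culture pair was not tested.

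Reversing the sign of arrays gives only 4 choices for each mutant, too few for a share under 0.05: the real signs gave the most genes in L3733A, SRR3413_L3733A and G3745 (1 of 4 in each), and the highest other count was 0. The differences between mutants have 10 splits each, also too few, with 1 of 10 reaching the real count in each and 0 as the highest other.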

How the results depend on the processing

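Alternatives chosen only after the data were seen were kept outlier spots, log ratios scaled between arrays, a dye term per slide, and slide blocks for the lists. Named genes kept direction and side of the threshold in 8048 of 8712 values, with 655 weaker, 2 stronger and 7 reversed; leaving out each array kept 5638 of 6570, with 927 weaker, 3 stronger and 2 reversed. Gene lists kept theirs in 1241 of 1435 values (127 weaker, 65 stronger, 2 reversed) and, leaving out arrays, in 1786 of 1845 (21 weaker, 38 stronger). The cause was not tested for any change below, except where fewer arrays, a stricter threshold or the construction shows it.

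Genes changed in L3733A (2012): 0 with the 7 arrays of the larger design, where 1 L3733A array remains, 3033 with array weights, 1013 at adjusted p under 0.01, 419 with at least 2-fold, and 558 to 2780 leaving out each array. Those in SRR3413_L3733A (2482): 1638 with 7 arrays, 4033 with weights, 1605 with slide as a random block, 1313 under 0.01, 441 with 2-fold, 814 to 3215 leaving out each array. For G3745 (2864): 4611 with weights, 23 with its own arrays only and no dye term, 1438 under 0.01, 447 with 2-fold, 723 to 3296 leaving out each array. The weights did not converge (71.6 for array 1 of G3745), so those counts are no guide. SRR3413_L3733A against L3733A (1061): 1893 scaled between arrays, 686 with a dye term per design, 518 per slide, 0 with 7 arrays, 2564 with weights, 600 with slide as a random block and 1 as a fixed block, 1682 with only the compared arrays and no dye term, 255 under 0.01, 1618 under 0.10, 202 with 2-fold, and 204 to 2008 leaving out each array. G3745 against L3733A (3206): 822 with 7 arrays, 2096 under 0.01, 1297 with 2-fold, 2415 to 3552 leaving out each array.

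The correlation of L3733A and SRR3413_L3733A (0.661) was 0.584 with processed signals or the deposited matrix and 0.518 by rank. With an estimated correlation 0 lists passed in L3733A, SRR3413_L3733A and G3745, against 20, 18 and 20; leaving out arrays gave 16 to 21, 17 to 21 and 18 to 24. Fry passed 20, 25, 24, 1 and 31. The replicate block left 2011, 2478, 2865, 833 and 3152 genes and 18, 16 and 20 lists. Deviations of arrays with equal numbers from their group means correlated at -0.49 to 0.53. For L3733A and SRR3413_L3733A they correlated at 0.02, 0.53 and 0.3, and at 0.1, -0.46 and -0.11 with the dye term removed. Equal numbers carry the same dye in these 2 mutants, so whether numbers pair arrays cannot be told.

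Reversed values: with slide as a fixed block, cytosolic ribosomal proteins -0.21 and unfolded protein response -0.87 between SRR3413_L3733A and L3733A. With median centring TRA1 in L3733A -0.01, ACT1 in G3745 -0.01 and ACT1 against L3733A -0.02. With processed signals or the matrix SPO19 in G3745 0.13 (below background in both channels) and MLS1 between SRR3413_L3733A and L3733A 0.08. TRA1 in G3745 ranged from -0.01 (without array 2) to 0.57 leaving out each array, and against L3733A from -0.09 to 0.55.

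Not run as alternatives were a median over probes (each gene has 1) and probes of both designs only (all are on both). Nor was quantile scaling of average signal, which leaves log ratios as they are and was used for the channel signals only. Slide as a fixed block for a mutant against its reference was not estimable. Weak signal limits 272 probes below background in both channels on every array, 924 below in either on any, and saturation 19.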

Other observations

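The channel comparisons below were chosen only after the results were seen. Genes of SAGA and NuA4 subunits, the complexes that hold Tra1, passed as lists in no mutant with camera, while fry passed SAGA in L3733A (up, adjusted p = 0.0465) and NuA4 in SRR3413_L3733A (down, adjusted p = 0.049). SAGA medians were 0.09 in L3733A, -0.02 in SRR3413_L3733A and 0.12 in G3745 (camera adjusted p = 0.192, 0.745 and 0.626). In G3745 the SAGA genes HFI1 (-0.78 ± 0.10) and UBP8 (-0.58 ± 0.11) fell and SGF73 (0.59 ± 0.14) rose. NuA4 medians were 0.05, -0.15 and 0.10 (camera adjusted p = 0.882, 0.393 and 0.432), and EAF1 rose in G3745 (0.46 ± 0.10). Galactose genes stood at -0.15, -0.21 and 0.19 (camera adjusted p = 0.0723, 0.393 and 0.318).

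Of 28 iron genes 4 rose, 2 fell and 22 did not pass in L3733A, where SIT1 (1.34 ± 0.12) and FTR1 (1.17 ± 0.16) joined FET3 and MRS4 fell (-0.85 ± 0.08), with a list median of -0.03 (camera adjusted p = 0.882). CYB2 fell in L3733A (-2.55 ± 0.17) and rose in G3745 (1.67 ± 0.17), and the lactate transporter gene JEN1 rose in G3745 (2.38 ± 0.26). The alpha-cell list stood at 0.69 in G3745 (camera adjusted p = 0.0577), where MF(ALPHA)1 (1.08 ± 0.23) and SAG1 (0.80 ± 0.13) rose. The a-cell genes MFA1 (-0.51 ± 0.12), STE6 (-0.47 ± 0.15) and ASG7 (-0.57 ± 0.18) fell in SRR3413_L3733A, with a list median of -0.39 (camera adjusted p = 0.129). In the same mutant INO1, of inositol synthesis, fell (-1.13 ± 0.31) while its list stood at 0.16 (camera adjusted p = 0.062), and MGA1 rose by at least 2.21-fold, its reference being below background. Cell wall genes stood at 0.05, 0.23 and 0.25 in L3733A, SRR3413_L3733A and G3745, oxidative phosphorylation at 0.01, -0.08 and 0.10, and hexose transporters at -0.09, -0.12 and 0.15. Zinc genes stood at -0.11, -0.16 and 0.03, pheromone response genes at 0.02, -0.15 and 0.03, and telomere genes at 0.10, 0.00 and 0.15. The lists of SAGA, NuA4, galactose, mating type, pheromone response, inositol, cell wall, oxidative phosphorylation, hexose transporter, zinc and telomere genes passed in no comparison with camera, though fry passed some of them.

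URA3, a common plasmid marker, had log2 signals of 13.5 to 14.6 in the 6 channels of CY3019 and CY3020 on slides 2 and 3 and of 10.4 to 10.7 in the 8 channels of the other strains there. PHO84 was higher in CY2706 than in CY3020 by 3.90 on slide 2 and 4.19 on slide 3, GTT2 by 5.72 and 6.31, and OYE3 by 5.50 and 6.04. These are channel signals with no test. CY2706 minus CY3020 on slide 2 correlated at 0.733 with the same difference on slide 3. Inositol and phospholipid genes were lower in CY2706 than in CY3020 (-0.76 and -1.21), and lower by a like amount in L3733A (-1.08) and SRR3413_L3733A (-1.04).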
